A study of Mus musculus with 45 samples.

How the data were processed

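RNA of 45 single mouse oocytes was sequenced. Per the labels' protocols, each oocyte was lysed on its own and the libraries were made with the NEBNext Single Cell/Low Input RNA kit, with 16 PCR cycles for the cDNA and 8 for the library. The oocytes came from reconstituted chimeric follicles (RCF), in which an oocyte is placed into a follicle whose own oocyte had been taken out and the follicle is then cultured, or from young mice as controls. The groups were taken from the labels: young oocytes in young somatic cells (YY, n = 11), aged oocytes in young somatic cells (AY, n = 6), aged oocytes in aged somatic cells (AA, n = 12), young oocytes cultured in vitro (in vitro young, n = 8) and young oocytes without culture (in vivo young, n = 8).

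The deposited table held whole-number counts of reads per gene for 55357 gene identifiers, not normalized. Per the submitters' processing notes, STAR 2.7.8a, HTSeq 0.11.0 and the mouse build mm39 were used. Whether the counting used strand, and how reads shared between near-identical genes were treated, is not given in the sources used here. Coordinates are those of the deposited table, on mm39, counted from 1. Sample columns were matched to samples through the library number in the descriptions.

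Total counts per library ranged from 418703 to 2201980. No pair of libraries of a group agreed within counting noise (lowest chi-square per degree of freedom 1.98), a check that finds counts deposited more than once but not repeat libraries of 1 oocyte. Each library was counted as 1 sample because the labels name each as a replicate. The reads carry no molecular identifiers, so counts of amplified cDNA are not counts of molecules.

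The main test was edgeR 4.0.16 in R 4.3.3 with TMM scaling, filterByExpr by group (minimum count 10, minimum total 15), a robust quasi-likelihood fit and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. AA, AY and YY shared 1 fit of 29 libraries. YY and the controls shared another of 27 libraries. Standard errors of log2 fold changes were derived from the F statistic. CPM values per group are TMM-scaled and are given as mean and SD over libraries, except where unscaled CPM are named. Gene lists (25 lists, 724 entries, of which 710 matched a symbol of the table) were written before the data were examined and tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Lists with fewer than 3 tested genes were not tested. A held-out age score was the mean z score of log CPM (prior count 2) of genes higher in AA minus that of genes lower in AA. Its genes were chosen on odd-numbered AA and YY libraries and it was compared, with an exact permutation test, between AY and the even-numbered libraries.

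Genes were named by a rule fixed before the data were examined. For comparisons among YY, AY and AA, the rule took the 8 genes with the smallest p in each direction. These had to be called, to change by a log2 of at least 1, to reach a mean of 10 CPM in the higher group and to hold at least 5 counts in a share of 0.75 of its libraries. Predicted and clone-derived gene models were left out. Up to 2 called members of each list were added, with no fold or CPM condition. Comparisons of the controls took 5 genes per direction and 1 per list. Genes named outside the rule are marked as chosen after their values were seen. Some genes that the rule takes are not reported here, and counts of named genes include them.

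The edgeR fit was tested on simulated data, with negative binomial counts at the real means, library sizes and dispersions and 200 changed genes. For AA against YY, over 8302 genes, it recovered 47% of the 1.5-fold changes, 81.2% of the 2-fold changes and 100% of the 4-fold changes, with 9 false calls. For AY against AA, over 8275 genes, the shares were 35.4%, 76.9% and 96.7%, with 8 false calls. For AY against YY, over 8288 genes, they were 43.1%, 65.2% and 97%, with 4 false calls. For YY against in vitro young, over 8559 genes, they were 24.2%, 80% and 98.4%, with 5 false calls. For in vitro young against in vivo young, over 8556 genes, they were 26.9%, 66.2% and 100%, with 7 false calls.

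Alternatives fixed before the data were examined were RLE size factors, DESeq2 1.42.0, limma voom with quality weights, 2 other filters on low counts, other sets of libraries in the fit, a replicate block, the number of genes detected as a covariate, the removal of mitochondrially encoded genes, leaving out each library in turn, and YY libraries of either numbering series alone. Libraries were left out in turn, and the YY series taken alone, only for comparisons among YY, AY and AA. Alternatives chosen after seeing the data used sets of libraries with the same pattern of all-or-nothing genes, summed or as a random or fixed block, and a correction for transcript GC content and length. GC content and length came from the GENCODE M21 transcripts, matched by gene identifier, and no coordinate of that annotation was used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.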

Results

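Read counts per gene were analysed for 45 mouse oocytes, each sequenced as its own library. Chimeric follicles were built so that the age of the oocyte and the age of the somatic cells around it could be set apart: 11 libraries held young oocytes placed in young somatic cells (YY), 6 held aged oocytes in young somatic cells (AY) and 12 held aged oocytes in aged somatic cells (AA). Another 8 libraries came from young oocytes cultured in vitro and 8 from young oocytes without culture. Total counts per library ranged from 418703 to 2201980, with means of 785644 in YY, 824217 in AY, 833878 in AA, 1169000 in the cultured and 1122938 in the uncultured young oocytes. The labels call each oocyte a biological replicate and name no animal, so p-values measure only the spread between these samples, which may be technical or come from few animals. The meiotic stage at collection is not given in the sources used here, so a difference in stage between groups was not examined. Each group, controls included, held its own range of library numbers. A difference between numbering series therefore cannot be told apart from a difference between groups in any comparison.

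The oocytes of a group were not alike for a small set of genes that were either fully present or nearly absent. Oog3, an oocyte-specific gene of the PRAME family on chromosome 4 (143884127 to 143889233, mm39), had 0 counts in 11 libraries and at least 967 counts in the other 34. In all, 11 genes on 10 chromosomes showed such a gap of at least 3 log2 units, among them Tmem14c, Mtfr2, Bfsp1 and Rhbdf1, and they divided the 45 libraries into 10 patterns. AA held 2 of these patterns (9 and 3 libraries), AY held 2 (4 and 2) and YY held 4, and no pattern occurred in more than 1 of AA, AY and YY. Among the controls patterns recurred: 1 was found in in vivo young, in vitro young and YY, and others in both control groups or in in vitro young and YY. A pattern is therefore not shown to be 1 animal. The division was chosen after seeing the data, and it is not known to be the right level of replication. Counts of called genes are also given with the libraries of each pattern in a group treated as 1 sample. Oog3, Gm4350 and Pramel48 belong to families of near-identical copies, so their counts are uncertain.

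**Figure D1:**
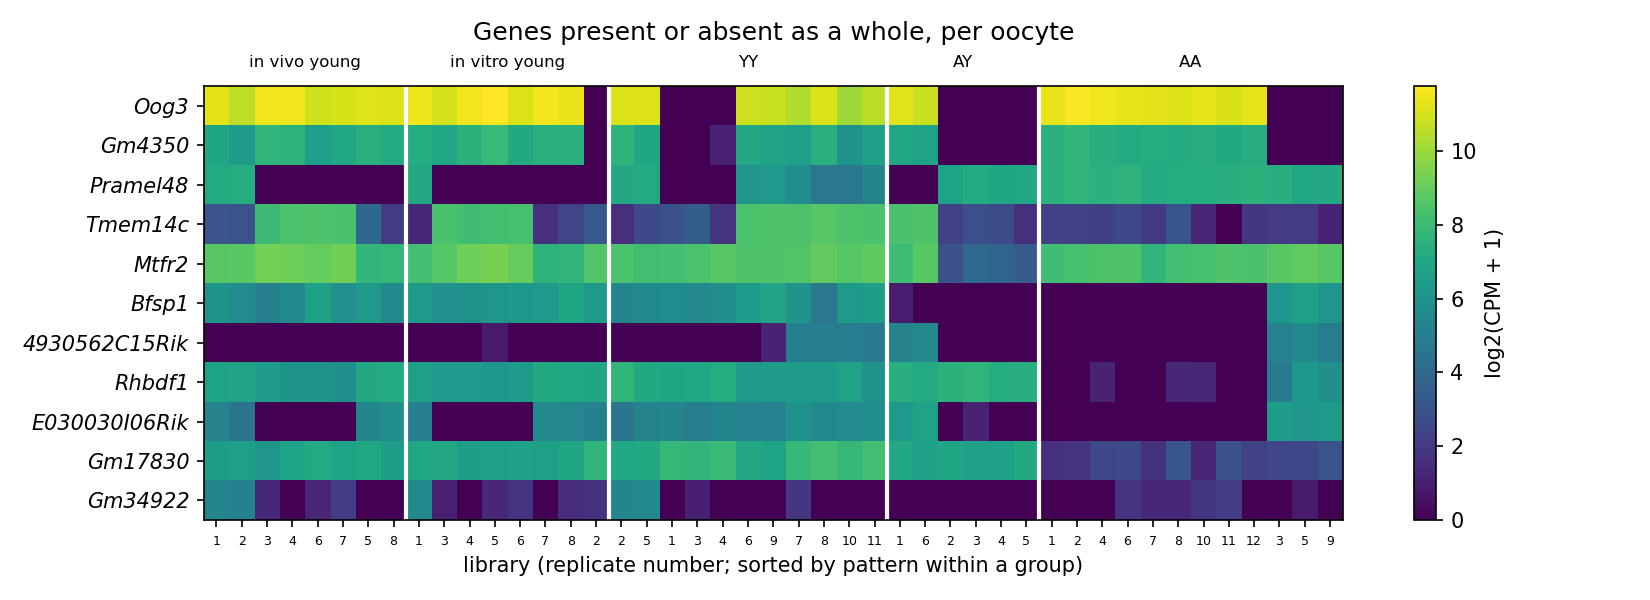
Level of the 11 all-or-nothing genes as log2(CPM + 1), with 1 row per gene and 1 column per library, grouped by label and sorted by pattern within a group. Oog3 is absent in AA replicates 3, 5 and 9 and in AY replicates 2, 3, 4 and 5, and Rhbdf1 is nearly absent in the other 9 AA libraries.

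The first comparison asked what differed between aged oocytes in aged somatic cells and young oocytes in young somatic cells. Ncapg, a condensin subunit, rose by a log2 of 1.33 ± 0.12 (SE), from 289 ± 82 CPM in YY (SD, n = 11) to 722 ± 66.1 CPM in AA (SD, n = 12). Thg1l, a tRNA-histidine guanylyltransferase, rose by 1.5 ± 0.16, and Nap1l5, an imprinted gene, by 2.55 ± 0.37. Tet3, the oocyte enzyme that oxidises 5-methylcytosine, fell from 851 ± 239 CPM to 416 ± 59.3 CPM, a log2 change of -1.04 ± 0.12. Dazl, an RNA-binding regulator of translation in germ cells, changed by -0.81 ± 0.09. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2348 of 8533 genes were called, of which 1090 were higher and 1258 lower in AA. At least 2-fold changes were fewer, with 63 higher and 286 lower.

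The other genes with the smallest p values that rose were Iars (1.13 ± 0.15), Cdc34b (1.22 ± 0.16), Tcn2 (1.07 ± 0.17) and Capza1 (1.19 ± 0.19). Those that fell were Baz2a (-1.21 ± 0.14), Tiam1 (-1.18 ± 0.14), Ice1 (-1.14 ± 0.13), Wasf2 (-1.08 ± 0.13), Tsc22d4 (-1.93 ± 0.24), Hmga1b (-1.24 ± 0.16) and Sf3a2 (-1.97 ± 0.26). For each of the 16 leading genes of the naming rule, Tet3, Ncapg, Thg1l and Nap1l5 included, all 12 AA libraries lay on 1 side of the YY median. The rule chose these genes by p and size of change in the same libraries, so this separation is no independent support. Ncapg lies on chromosome 5 (45827261 to 45857888) and Tet3 on chromosome 6 (83339355 to 83436066). Cdc34b and Hmga1b have near-identical relatives in the genome, so their counts are uncertain.

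Regulators of chromatin had more lower than higher members: 13 of 26 measured members fell and 1 rose, or 13 and 3 when adjusted over the list alone. Kmt2d, a histone H3K4 methyltransferase, changed by -0.89 ± 0.12, Suz12 of the Polycomb complex by -0.69 ± 0.11, the maintenance methyltransferase Dnmt1 by -0.73 ± 0.14 and the deacetylase Sirt1 by -1.1 ± 0.25. Dnmt3l was the 1 member that rose, by 0.32 ± 0.09. Suz12, Dnmt1, Sirt1 and Dnmt3l were chosen after their values were seen. The camera test gave an adjusted p of 0.00108 and this list alone held with an estimated correlation (adjusted p = 0.0394 with an estimated correlation).

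Genes of the subcortical maternal complex, an oocyte protein assembly needed for early cleavage, were higher: 6 of 10 rose and none fell, or 6 and 1 when adjusted over the list alone. Nlrp5 (MATER) rose from 550 ± 296 CPM in YY to 1420 ± 521 CPM in AA, by 1.37 ± 0.27, Nlrp9a by 1.16 ± 0.22 and Nlrp2 by 1.05 ± 0.21, while Ooep was at -0.21 ± 0.08 (adjusted p = 0.0536, edgeR with Benjamini-Hochberg). The camera test gave an adjusted p of 0.00108, and an adjusted p of 0.12 with an estimated correlation. Nlrp2 and Ooep were chosen after their values were seen. Nlrp genes form a family of similar sequences, so reads may be split between them.

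Proteasome subunits rose in 13 of 30 cases with none falling, or 13 and 1 when adjusted over the list alone, led by Psmc1 (0.43 ± 0.09) and Psmd2 (0.76 ± 0.15). The list had an adjusted p of 0.00188 in camera and an adjusted p of 0.153 with an estimated correlation. Among kinetochore and spindle checkpoint genes 8 of 28 rose and 1 fell, or 9 and 1 when adjusted over the list alone. Bub1 rose by 0.73 ± 0.14 and Cdca8 by 0.33 ± 0.07, whereas Incenp, chosen after its values were seen, fell by 0.55 on the log2 scale. That list had an adjusted p of 0.00271 in camera and an adjusted p of 0.153 with an estimated correlation. In glycolysis and the citric acid cycle 9 of 23 genes rose and 2 fell, or 10 and 2 when adjusted over the list alone, with an adjusted p of 0.00271 and an adjusted p of 0.202 with an estimated correlation. Ldhb, the lactate dehydrogenase subunit of oocytes, rose from 5750 ± 998 to 8900 ± 852 CPM, by 0.63 ± 0.09, and Sucla2 rose by 0.54 ± 0.09.

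Mitochondrial dynamics genes rose in 8 of 23 cases and fell in 1, with the same counts when adjusted over the list alone, among them the fission factor Dnm1l (0.7 ± 0.1) and the transport adaptor Rhot1 (0.9 ± 0.14). The list had an adjusted p of 0.0244 in camera and an adjusted p of 0.12 with an estimated correlation. Of 18 genes of communication between oocyte and somatic cells, 7 fell and 3 rose, or 7 and 3 when adjusted over the list alone, including the junction proteins Cdh1 (-0.79 ± 0.12) and Ctnnb1 (-0.92 ± 0.14), and the camera adjusted p was 0.118. Members called in lists that did not pass camera included the cyclin Ccnb2 (0.42 ± 0.07), the deadenylase Cnot6l (-0.9 ± 0.14), the zona pellucida gene Zp2 (0.56 ± 0.09), the cohesin protector Sgo2a (0.7 ± 0.12), separase Espl1 (-0.93 ± 0.18), Casp8 (0.89 ± 0.16), Tacc3 (0.63 ± 0.11), Atp5g1 (-1.35 ± 0.23) and Ern1 (-0.65 ± 0.1). Nuclear genes of oxidative phosphorylation had 10 of 73 members risen and 2 fallen, also when adjusted over the list alone, with a median of -0.02, a mean of 0.01 and a camera adjusted p of 0.56. Meiotic maturation genes had 6 of 26 risen and 10 fallen, or 6 and 11 when adjusted over the list alone (camera adjusted p = 0.564).

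Mitochondrially encoded transcripts made up 0.122% ± 0.034 of counts in AA (SD, n = 12) and 0.272% ± 0.162 in YY (SD, n = 11), a difference larger than chance in a two-sided permutation test (p = 0.00342, adjusted p = 0.00855 over 5 comparisons). All 8 tested genes were lower in AA and 3 were called, mt-Nd4 at -1.21 ± 0.39, mt-Nd5 at -1.1 ± 0.37 and, chosen after its values were seen, mt-Nd6 at -1.37 ± 0.49 (none were called without YY replicate 7 or without YY replicate 10), and the list did not pass camera (adjusted p = 0.164). The YY libraries differed among themselves: those numbered S225 to S231 held 0.387% ± 0.116 (SD, n = 6) and those numbered S198 to S202 held 0.133% ± 0.07 (SD, n = 5), which did not differ from AA in an exact permutation test (p = 0.652). Against S198 to S202 alone the median log2 change of these genes turned to 0.26 and none was called. With the pattern as a random block, mt-Nd4 (limma voom, adjusted p = 0.152) and mt-Nd5 (adjusted p = 0.255) lost their call.

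Transcripts typical of granulosa cells, the somatic cells that enclose the oocyte, were higher in AA. Inha, the inhibin alpha subunit, rose from 6.71 ± 6.68 CPM in YY to 50.4 ± 36.4 CPM in AA, by 2.78 ± 0.49, Inhba by 1.99 ± 0.47 and Serpine2, which oocytes of every group also expressed and which was chosen after its values were seen, by 0.5 ± 0.12. With 3 of 5 measured markers risen over all genes and when adjusted over the list alone, the list had a camera adjusted p of 0.0237 and an adjusted p of 0.12 with an estimated correlation. Summed unscaled CPM of theca and stroma markers were 15.1 ± 6.7 in AA and 13.6 ± 5.16 in YY, of immune markers 15.4 ± 6.36 and 12 ± 4.45, and of endothelium and blood markers 86.4 ± 17.9 and 75.7 ± 22.4 (SD, n = 12 and 11).

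The number of called members changed in other fits and was lower in most. Against the 5 YY libraries S198 to S202 alone, 0 proteasome genes and 0 granulosa markers were called. In that fit 1 kinetochore gene and 1 gene of the maternal complex were higher and 3 chromatin regulators were lower, with 5 mitochondrial dynamics genes higher, and 3 glycolysis genes higher and 1 lower. With the pattern as a random block, 5 proteasome, 4 kinetochore and 4 mitochondrial dynamics genes, 1 granulosa marker and 6 glycolysis genes were higher, and 6 genes of the maternal complex were higher as before. Lower in that fit were 8 chromatin regulators, 1 kinetochore gene and 1 glycolysis gene. After correction for GC content and length, 6 proteasome genes were higher and 2 lower, 5 mitochondrial dynamics genes were higher, and 9 chromatin regulators were lower and 1 higher. The maternal complex then had 6 higher and 1 lower, and the counts for kinetochore, glycolysis and granulosa genes equalled those of the main fit. No member of these lists was called with the libraries of each pattern summed.

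The count of 2348 fell to 1103 with the pattern as a random block, to 451 against the YY libraries S198 to S202 alone (3151 against S225 to S231 alone), and to 2 (Thg1l and Gm17830) with the libraries of each pattern summed, where 1735 genes had an unadjusted p under 0.05. Gm17830 is one of the 11 genes that define the patterns. It was nearly absent in all 12 AA libraries and present in every other library, so it divided no group. Because it was picked for a large gap between libraries, its call is not independent of that choice. Thg1l was the 1 other gene called. That last fit recovered 68.7% of 2-fold and 23.9% of 1.5-fold changes in simulated data of independent libraries over 8533 genes. The simulation lacked the larger spread of the real sums, so it cannot tell whether few sums at that spread lose the larger changes. Of 345 genes called at 2-fold or more in the main fit that do not define a pattern, 1 was called in the sums over the same 8533 genes. All 345 kept their direction, with a median size of 1.19 in place of 1.23. The sums hold the same libraries on which these genes were chosen. Kept direction and size are therefore no independent support, here and in the comparisons below. The sums of a group varied more (biological coefficient of variation 0.214) than sums of independent simulated libraries (0.138). Gm17830, a long non-coding RNA gene on chromosome 17 chosen after its values were seen, stood at 4.67 ± 2.19 CPM in AA and 203 ± 63.9 CPM in YY, a log2 change of -5.4 ± 0.2.

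**Figure D2:**
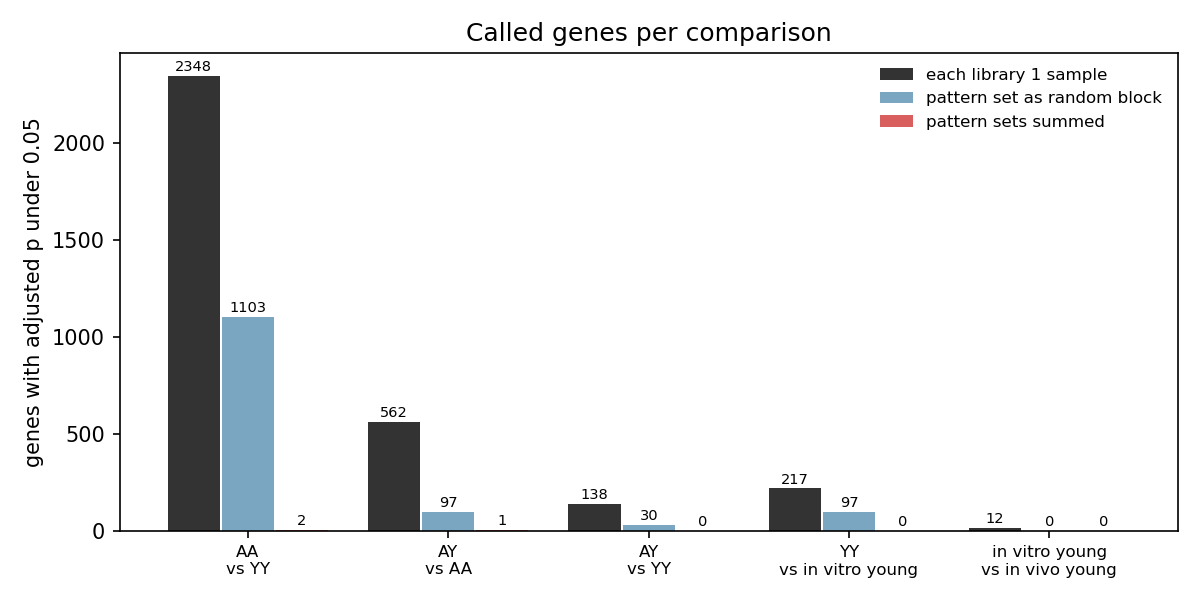
Number of genes with an adjusted p under 0.05 in each comparison, with each library as 1 sample, with the pattern of all-or-nothing genes as a random block, and with libraries of a pattern summed. The AA against YY bars stand at 2348, 1103 and 2 genes.

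The comparison of AY with AA asked what differed in aged oocytes when the somatic cells were young. Thg1l was lower in AY, at 23.1 ± 2.69 CPM (SD, n = 6) against 63.6 ± 15.4 CPM in AA (SD, n = 12), a log2 change of -1.46 ± 0.19, and stood at 23.2 ± 6.67 CPM in YY. Cst3, the protease inhibitor cystatin C, rose by 1.34 ± 0.16 to 196 ± 44.9 CPM. Tet3 rose by 0.67 ± 0.14, Kmt2d by 0.59 ± 0.15 and Hmga1b by 1.13 ± 0.19, all of which had fallen in AA against YY. Ldhb fell by 0.49 on the log2 scale and Dnm1l by 0.52. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 562 of 8533 genes were called, 300 higher and 262 lower in AY, with 112 and 48 of them changed at least 2-fold.

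Other genes with the smallest p values were Cracr2a (4.97 ± 0.69, from 0.379 ± 0.69 to 18.5 ± 10.2 CPM), Rbm34 (3.67 ± 0.57), Cdc42bpb (1.91 ± 0.32), Dok4 (1.44 ± 0.25), Fam131a (1.28 ± 0.23) and Dtx2 (1.07 ± 0.19) among those that rose. Among those that fell were Elovl7 (-1.15 ± 0.2), Ighg1 (-1.36 ± 0.25), Vps50 (-1.07 ± 0.2), Qrfprl (-1.23 ± 0.24), Zfpm2 (-1.6 ± 0.32), Snapin (-1.3 ± 0.27) and Rmnd1 (-3.23 ± 0.67). Of list members, the lactate carrier Slc16a1 (1.19 ± 0.22), Psmd3 (0.97 ± 0.24), Cdc25b (0.95 ± 0.28), Dazl (0.41 ± 0.1) and the oocyte transcription factor Lhx8 (0.39 ± 0.11) rose, while Nlrp9a (-0.95 ± 0.26), Ckap5 (-0.61 ± 0.16), Wee2 (-0.39 ± 0.12) and Daam1 (-1.5 ± 0.34) fell. AY replicate 1 held by far the highest level of Dtx2, Psmd3 and Cdc25b within AY, and without that library 24 of the 40 named genes kept their call.

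Of the lists, 2 passed camera. The mitochondrially encoded genes were higher in AY, with a median log2 change of 1, none of 8 called over all genes and 3 when adjusted over the list alone (camera adjusted p = 8.3e-04, and adjusted p = 0.604 with an estimated correlation). Their share of counts was 0.242% ± 0.087 in AY (SD, n = 6), and the exact permutation test against AA gave p = 0.000215 (adjusted p = 0.00108). Kinetochore and checkpoint genes were lower, with 3 of 28 fallen over all genes and when adjusted over the list alone, Bub1 by 0.56 and Cenpe by 0.35 on the log2 scale (camera adjusted p = 0.0174, and adjusted p = 0.604 with an estimated correlation). None of the 28 was called without AY replicate 1, 3 or 6 or without AA replicate 5. The same held with the pattern as a random block and after correction for GC content and length. Among the 28, 1 was called without AA replicate 3, 7 or 12. Granulosa markers did not pass, with none of 5 called, and Inha stood at 44.6 ± 31.7 CPM in AY and 50.4 ± 36.4 CPM in AA.

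**Figure D3:**
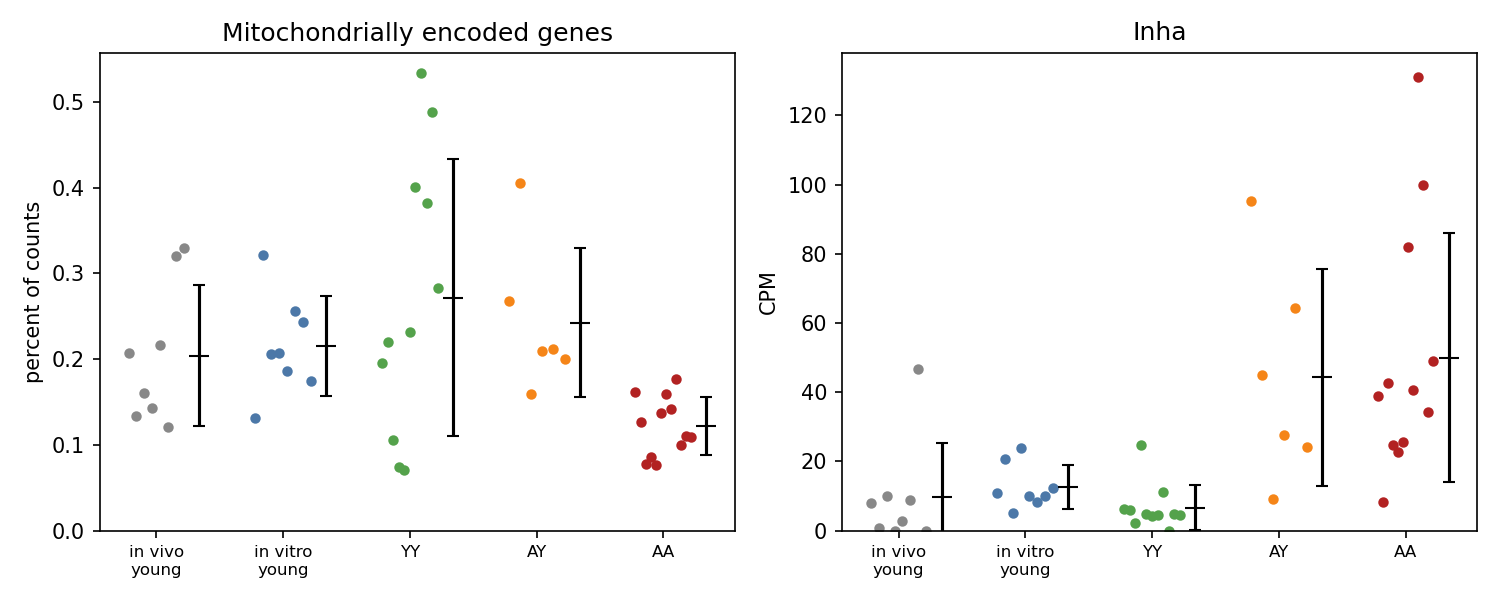
Percent of counts from mitochondrially encoded genes (left) and CPM of Inha (right), with 1 point per library and the mean with SD beside each group. The AA libraries lie between 0.077% and 0.177%, and mean Inha is 6.71 CPM in YY, 44.6 CPM in AY and 50.4 CPM in AA.

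Genes called in both comparisons mostly moved in opposite directions. Of the 1090 genes higher in AA than YY, 183 were lower in AY than AA, where independent lists would share 33.5, and of the 1258 lower in AA, 236 were higher in AY, where independent lists would share 44.2. In the same direction 0 and 2 genes were shared. Because the AA libraries enter both comparisons, the fold changes are correlated by chance. The correlation across genes was -0.71, against -0.4 in simulations without effects and -0.492 in simulations that kept the pattern sets, and the covariance was -0.154 against -0.02 and -0.0432. With AA libraries split so that none served both comparisons, the correlation lay between -0.541 and -0.362 and the covariance between -0.0971 and -0.0849, and 86.7% to 89.6% of the genes called between AA and YY still had opposite signs, compared with 94.1% without the split. Genes are not independent replicates. The split also leaves in whatever all AA libraries share, such as their numbering series. It cannot tell that from an effect of the somatic cells. Of the 16 leading genes of AA against YY, 11 were called in the opposite direction in AY against AA, among them Baz2a (0.85 in AY against AA), Tsc22d4 (1.49), Sf3a2 (1.59), Iars (-0.79) and Capza1 (-0.84), whereas Cdc34b (0.02) and Nap1l5 (-0.28) were not called. These genes were chosen on the AA libraries that serve both comparisons, which favours opposite signs, and the split was not applied to this count.

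The count of 562 fell to 203 without AY replicate 1 and to 306 without AY replicate 6, the 2 libraries of the smaller AY pattern. The gene count was 848 with limma voom, 876 with only these groups in the fit, 318 with the larger AA pattern set, 147 with the larger AY pattern set, 97 with the pattern as a random block and 1 with libraries of each pattern summed, where 950 genes had an unadjusted p under 0.05. That 1 gene is Gm17830, present in all 6 AY libraries and nearly absent in all 12 AA libraries. It is one of the 11 genes picked for a large gap, and no gene outside these 11 was called by edgeR in the sums. Of 157 genes called at 2-fold or more that do not define a pattern, all kept their direction there, with a median size of 1.31 in place of 1.23, and 140 had an unadjusted p under 0.05.

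The comparison of AY with YY asked what still differed between aged and young oocytes when both were in young somatic cells. Inha was higher in AY by 2.63 ± 0.55, Gja1, the gap junction protein connexin 43, by 2.88 ± 0.68 (17.1 ± 14.8 against 2.16 ± 2.36 CPM), and Ldha by 1.6 ± 0.38. Granulosa cells also express Inha and Gja1, and Gja1 was higher in AA too (27.5 ± 30.3 CPM), so these changes are not shown to lie in the oocyte. The cohesin protector Sgo2a rose by 0.83 ± 0.14, Cdc34b by 1.24 ± 0.18 and Zp2 by 0.52 ± 0.11, all of which were also higher in AA than in YY. Timd4 fell by 1.46 on the log2 scale and the tight junction gene Tjp1 by 1.33. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 138 of 8533 genes were called, 61 higher and 77 lower in AY.

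Further genes of the naming rule that rose were Slc12a8 (2.71 ± 0.45), Nap1l5 (2.28 ± 0.42), Ms4a6d (1.05 ± 0.22), Patj (1 ± 0.21), Entpd6 (1.55 ± 0.34), Serpine2 (0.76 ± 0.14), Aldoa (0.45 ± 0.11) and Ctsb (0.61 ± 0.16). Those that fell were Myh11 (-1.14 ± 0.23), Anp32e (-1.49 ± 0.31), Klhl1 (-1.31 ± 0.28), Nedd4 (-1.2 ± 0.26), Slx4ip (-1 ± 0.22), Rn18s-rs5 (-1.37 ± 0.29), Cpeb4 (-0.94 ± 0.22), Esco1 (-0.31 ± 0.08), Oosp3 (-0.41 ± 0.11) and Daam1 (-1.3 ± 0.35). Slc12a8 was above the YY median in 4 of 6 AY libraries only. Rn18s-rs5 carries ribosomal RNA sequence, so its counts depend on ribosomal reads.

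Of 8 lists that passed camera, granulosa markers had 2 of 5 members risen (3 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.00317, and adjusted p = 0.0539 with an estimated correlation). Glycolysis and citric acid cycle genes had 2 of 23 risen, also over the list alone (adjusted p = 0.00317, and adjusted p = 0.159 with an estimated correlation). Genes of communication with somatic cells had 1 of 18 risen (Gja1) and 1 fallen (Daam1), or 1 and 3 when adjusted over the list alone (adjusted p = 0.0278, and adjusted p = 0.0884 with an estimated correlation). Chromatin regulators, with a median of -0.25 and none of 26 called over all genes or adjusted over the list alone, had an adjusted p of 0.00317 and an adjusted p of 0.0539 with an estimated correlation. Proteasome (adjusted p = 0.00317), subcortical maternal complex (adjusted p = 0.00584), cholesterol synthesis (adjusted p = 0.0239) and mitochondrial dynamics genes (adjusted p = 0.0467) had no called member over all genes, with 3 higher and 1 lower in mitochondrial dynamics and none in the others when adjusted over the list alone, and the adjusted p with an estimated correlation was 0.159, 0.159, 0.0884 and 0.153. The subcortical maternal complex had a median of 0.25 that turned to -0.08 against the YY libraries S198 to S202 and to -0.01 with a replicate block. No glycolysis member was called without AY replicate 4, and no communication member without AY replicate 1, where 1 glycolysis gene and 1 granulosa marker were called. The share of mitochondrially encoded counts in AY (0.242%) lay between the 2 series of YY libraries (0.133% in S198 to S202 and 0.387% in S225 to S231). The test against all YY libraries did not pass (exact permutation test, p = 0.687). The median log2 change of these genes was 0.19 against all YY libraries, 1.31 against S198 to S202, -0.33 against S225 to S231 and -0.02 without AY replicate 6.

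The genes shared in direction with AA against YY were 37 higher and 52 lower, where independent lists would share 7.8 and 11.4. The YY libraries enter both comparisons, and the correlation of fold changes across genes was 0.487, against 0.429 and 0.386 in the simulations without effects, with a covariance of 0.0854 against 0.0218 and 0.032.

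The count of 138 became 85, 88 and 84 without AY replicates 2, 4 and 5, 79 with only these groups in the fit, 236 without a filter on low counts and 847 against the YY libraries S225 to S231 alone. Against S198 to S202 alone it was 134, of which 45 were among the 138, and 15 of 26 named genes lost their call. It was 30 with the pattern as a random block, where 20 of 27 named genes lost their call. Among these were Inha (limma voom, adjusted p = 0.21), Gja1 (adjusted p = 0.494), Ldha (adjusted p = 0.125) and Zp2 (adjusted p = 0.0988), while Cdc34b and Sgo2a kept their call. With libraries of each pattern summed the count was 0, where 617 genes had an unadjusted p under 0.05 in edgeR. All 44 genes called at 2-fold or more that define no pattern kept their direction in the sums, with a median size of 1.33 in both fits.

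A score of the genes that separated AA from YY placed AY between them. The score, built on 357 higher and 418 lower genes chosen on odd-numbered libraries, averaged 1.28 ± 0.41 in even-numbered AA (SD, n = 6), -0.14 ± 0.77 in AY (SD, n = 6) and -1.37 ± 1.19 in even-numbered YY (SD, n = 5). AY lay below AA by 1.42 (two-sided exact permutation test, p = 0.00649), with 5 of 6 AY libraries below every AA library. All 6 even-numbered AA libraries were of the larger AA pattern, which also gave libraries to the gene choice. Each YY pattern had both odd-numbered and even-numbered libraries. The score was therefore held out by library and not by pattern, and its p-values count libraries of 1 pattern as independent. Scores that kept the AA pattern sets apart, chosen after seeing the data, gave AY minus AA of -1.49 and -1.38. AY lay above YY by 1.23, which did not pass (two-sided exact permutation test, p = 0.0628). In alternatives chosen after seeing the data, that second difference turned to -0.27 (exact permutation p = 0.496) when genes were chosen on YY libraries S225 to S231 and compared in S198 to S202, and was 1.41 (exact permutation p = 0.00216, the smallest these samples can give) the other way round.

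**Figure D4:**
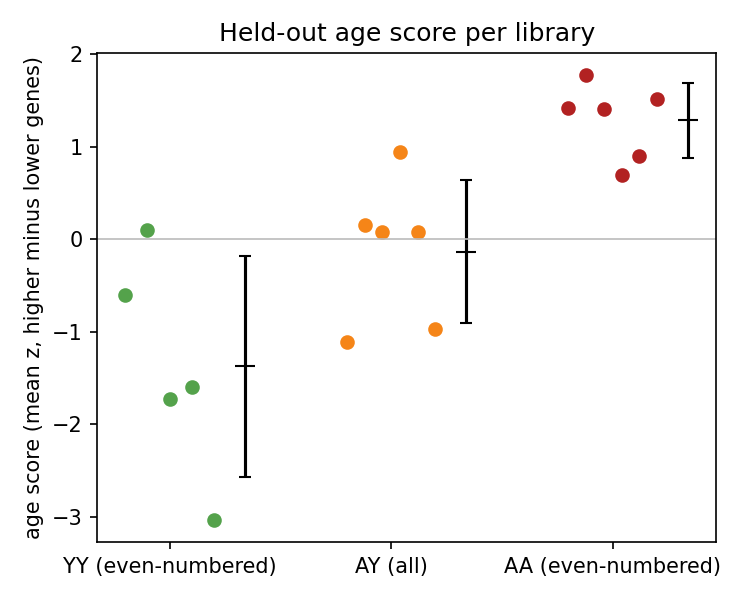
Held-out age score per library for even-numbered YY, all AY and even-numbered AA libraries, with the mean and SD beside each group. Means are -1.37, -0.14 and 1.28, and 5 of 6 AY libraries lie below all AA libraries.

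YY was compared with young oocytes cultured in vitro to see what reconstitution itself changed. Among genes of the heat shock and unfolded protein responses, 7 of 23 fell and none rose, or 10 fell and 2 rose when adjusted over the list alone. Hsp90aa1 went from 1140 ± 130 CPM in vitro (SD, n = 8) to 764 ± 65.1 CPM in YY (SD, n = 11), by -0.58 ± 0.08, Hspa5 by -1.13 ± 0.21, Hsp90ab1 by -0.67 ± 0.11 and Pdia3 by -0.62 ± 0.14, the last 3 chosen after their values were seen. The median of the list was -0.02 and its mean -0.22. The camera adjusted p was 1.6e-04, and the adjusted p was 0.0635 with an estimated correlation. With the number of genes detected as a covariate 2 members were called, and 5 with the pattern as a random block. YY libraries had fewer detected genes (14306 on average, 15435 in vitro) and lower summed granulosa markers (7.95 ± 4.51 and 17.3 ± 9.28 unscaled CPM, SD, n = 11 and 8, exact permutation p = 0.00561, adjusted p = 0.00935). The nucleoporin Ranbp2 fell by 1.89 on the log2 scale, Cenpf by 0.96, Zp2 by 0.88 and the clathrin heavy chain Cltc by 1.02. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 217 of 8749 genes were called, 68 higher and the rest lower in YY.

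The subcortical maternal complex was lower, with 2 of 10 fallen, or 5 when adjusted over the list alone, led by Padi6 (-0.84 ± 0.17), with a camera adjusted p of 4.7e-04 and an adjusted p of 0.226 with an estimated correlation. Its median of -0.54 turned to 0.1 among libraries with shared patterns, which were only YY S198 to S202 and in vitro young replicates 1 and 2. No member was called with the number of genes detected as a covariate. The genes with the smallest p values that rose were Fam131a (1.22 ± 0.22), Mier2 (1.29 ± 0.25), Sf3a2 (1.36 ± 0.29), Slc9a3r1 (1.11 ± 0.25) and Zc3h3 (1.25 ± 0.29), and Oog4 (-1.02 ± 0.16), Enpp5 (-1.03 ± 0.18) and Cd69 (-1.8 ± 0.34) fell. Of list members Ldhb (-0.59 ± 0.11), Ran (-0.94 ± 0.19), Brca1 (-0.94 ± 0.2), Ctsb (-0.7 ± 0.16) and Ezh2 (-0.33 ± 0.08) fell, and Fgf8 (0.6 ± 0.16) and Mos (0.26 ± 0.07) rose. Oog4 belongs to the same family of near-identical copies as Oog3, so its counts are uncertain.

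The count of 217 was 419 with DESeq2, 558 with limma voom and 378 with all 45 libraries in the fit, and it was 67 with the number of genes detected as a covariate. It was 97 with the pattern as a random block. Among libraries with shared patterns it was 45, of which 10 were among the 217, and 19 of 21 named genes lost their call. That fit held only the 5 YY libraries S198 to S202 and in vitro young replicates 1 and 2. The lost calls therefore cannot be told apart from an effect of fewer libraries or of 1 YY series. With libraries of each pattern summed the count was 0, where 950 genes had an unadjusted p under 0.05 in edgeR. All 39 genes called at 2-fold or more kept their direction in the sums, with a median size of 1.17 in place of 1.25.

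Culture itself was addressed by comparing in vitro with in vivo young oocytes, where few genes were called. The nucleolar transcription factor Ubtf rose from 8.28 ± 4.43 to 22.7 ± 6.24 CPM (SD, n = 8 each), by 1.41 ± 0.27, the thyroid hormone-binding protein Crym by 1.03 ± 0.22, the mitochondrial cyclophilin Ppif by 1.17 ± 0.25, Ctdp1 by 1.67 ± 0.36 and the proteasome subunit Psmd7 by 0.65 ± 0.14. All 10 genes of the subcortical maternal complex were lower in vitro, with a median of -0.44, none called over all genes and 2 when adjusted over the list alone, with a camera adjusted p of 1.9e-05 and an adjusted p of 0.132 with an estimated correlation. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 12 of 8749 genes were called, 11 higher and 1 lower, and 844 had an unadjusted p under 0.05. The count was 46 with DESeq2, 35 with limma voom, 29 without a filter, 20 with only these groups, 29 with all 45 libraries and 22 among libraries with shared patterns. It was 0 with the number of genes detected as a covariate, with the pattern as a random block and with libraries of each pattern summed, where 664, 603 and 678 genes had an unadjusted p under 0.05. All 4 genes called at 2-fold or more kept their direction in the sums, with a median size of 1.31 in place of 1.29.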

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

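Of 110 groups of values of single libraries checked (groups of 6 or 8 libraries), 6 held a library that stood far from the others of its group, and chance flags about 1 in 20 such groups. Among the AY libraries, replicate 1 stood out for Dtx2 at 225.9 CPM, where the others held 83.3 to 132 CPM, for Psmd3 at 99.9 CPM against 24.3 to 49.1 CPM, and for Cdc25b at 46.8 CPM against 15.1 to 25 CPM. AY replicate 6 stood out for Cdc34b at 619.9 CPM, where the others held 249 to 368 CPM, and AY replicate 4 for Aldoa at 215.5 CPM against 169 to 181 CPM. In vivo young replicate 5 held 23.9 summed CPM of granulosa markers, where the other 7 libraries held 7.9 to 12.7 CPM.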

How the results depend on the processing

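Alternatives that use the all-or-nothing patterns, the correction for GC content and length, and the age scores with genes chosen on pattern sets or on 1 series of YY libraries were chosen after seeing the data. With libraries of each pattern summed, the counts were 2 for AA against YY, 1 for AY against AA (Gm17830, which helps define the patterns, in both), and 0 for AY against YY, YY against in vitro young and in vitro against in vivo young. With the pattern as a random block they were 1103, 97, 30, 97 and 0. With the larger AA or AY pattern set alone, AY against AA gave 318 and 147. With shared patterns as a fixed block, YY against in vitro young gave 45 (10 of them also called in the main fit), in vitro against in vivo young 22, and Padi6 turned from lower in YY to 0.03. For YY against in vitro young that fit held only YY S198 to S202 and in vitro young replicates 1 and 2. In simulated libraries that were independent, the summed fit recovered 68.7% of the 2-fold and 23.9% of the 1.5-fold changes of AA against YY over 8533 genes, and 55.2% and 7.5% for AY against AA over 8533 genes. Of the genes called at 2-fold or more in the main fit that define no pattern, 345 and 157, the sums called 1 and 0, with 282 and 140 at an unadjusted p under 0.05 in edgeR. Whether few sums at the real spread account for that loss was not tested. The sums varied more between sets of a group (biological coefficient of variation 0.214) than in the simulations (0.138).

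Against YY libraries S198 to S202, AA gave 451, and against S225 to S231 it gave 3151. Against S225 to S231, AY gave 847, and against S198 to S202 it gave 134, a number close to 138 that held 45 of those genes. With only the groups compared, AY against AA gave 876, AY against YY 79 and in vitro against in vivo young 20. With limma voom, AY against AA gave 848, YY against in vitro young 558 and in vitro against in vivo young 35. DESeq2 gave 419 and 46 for the last 2 comparisons, all 45 libraries in 1 fit 378 and 29, and the number of genes detected as a covariate 67 and 0. Without a filter, AY against YY gave 236 and in vitro against in vivo young 29. The cause was not tested. The filter meant to be stricter kept more genes (9220 and 9135) than filterByExpr, so no stricter filter was run.

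With a replicate block the counts were 1908 for AA against YY, 585 for AY against AA, 138 for AY against YY, 43 for YY against in vitro young and 8 for in vitro against in vivo young, of which 1821, 345, 57, 37 and 4 were also called without it. The numbers were not taken as pairs, since the lowest correlation of a pair was under 0.1 in each comparison. Own numbers correlated best in 2 of 11, 1 of 6, 4 of 6, 1 of 8 and 2 of 8 cases, and for AY against YY pairs correlated at -0.11 to 0.15. Leaving out each library gave 1961 to 2514 genes for AA against YY, 203 to 607 for AY against AA (203 without AY replicate 1, 306 without AY replicate 6) and 84 to 155 for AY against YY (85, 88 and 84 without AY replicates 2, 4 and 5).

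The score kept AY below AA in all 5 alternatives. AY against YY gave 1.41 with genes chosen on S198 to S202 and -0.27 with genes chosen on S225 to S231. With an estimated correlation, 1 list was called for AA against YY in place of 7, and 0 in the other 4 comparisons in place of 2, 8, 2 and 1. With fry 12 were called for AA against YY, 0 for AY against AA and 0 for in vitro against in vivo young. Of the 57 genes named for AA against YY, 35 kept their call in every alternative fixed before the data were examined that tested them. Of those named for the other comparisons 22 of 40, 8 of 27, 8 of 21 and 0 of 5 did. Some fits did not test every named gene, such as the replicate block with 54 of the 57. The comparisons of the controls had fewer alternatives, without single libraries left out and without the YY series alone.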

Other observations

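All tests of explanations in this part were set down after the values that decide them, or related ones, had been seen, so they can exclude an explanation but not establish one.

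Granulosa markers other than Inha and Inhba were low in every group but not equal. Leaving out Serpine2, Nr5a2 and Cyp19a1, which in vivo young oocytes also held (17.3 unscaled CPM for Cyp19a1), the other 23 markers summed to 23 ± 10.1 unscaled CPM in AA (SD, n = 12), 26.1 ± 13.6 in AY (SD, n = 6) and 7.95 ± 4.51 in YY (SD, n = 11). Young oocytes cultured in vitro held 17.3 ± 9.28 (SD, n = 8), more than YY in an exact permutation test (p = 0.00561, adjusted p = 0.00935 over 5 comparisons), and uncultured young oocytes held 11 ± 5.4 (SD, n = 8). Of the 23 markers, 11 had a higher mean in AA than in YY. Nr5a1, Kitl, Lhcgr and Ptgs2 had a lower mean in AA, and the rest had no counts in either group. Hsd17b1, an enzyme of estradiol synthesis chosen after its values were seen, had means of 8.05 CPM in AA, 5.64 CPM in AY and 0.761 CPM in YY, and Amh, chosen in the same way, was at 0 counts in every library.

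The all-or-nothing genes divided libraries within a group. The tables argue against depth as the cause, since each library with 0 counts of Oog3, a gene with near-identical relatives, would hold at least 821 at the level of its group. They argue against consecutive handling of the libraries of a pattern, sorted by number, in AA (7 runs of 2 patterns), YY (8 runs of 4), in vivo young (5 runs of 3) and AY (3 runs of 2). In vitro young libraries formed 4 runs of 4 patterns (chance 0.0286 in random order), so order stays open there. No YY pattern occurred in both numbering series, nor did an in vivo young pattern occur in both S17 to S18 and S71 to S77, so a difference between series stays open in both groups. With a looser gap of 2 log2 units, which 18 genes met, mismatches between libraries at the 9 genes on odd-numbered chromosomes followed those at the 9 genes on even-numbered ones, with a rank correlation of 0.71 across 192 pairs within groups (permutation p = 1e-04, the smallest the permutations can give, highest permuted value 0.434). A candidate explanation, as a hypothesis, is inherited variation between donor animals, which the labels do not name.

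Part of the genes called between AA and YY may differ between donors and not with age. GC content and length are argued against as the whole source, as 1771 of 2348 genes were called again in the same direction after correction. So is the number of genes detected, with 2224 called again in the same direction. Pattern sets were also compared with 3 libraries each and the genes that define the sets left out. A YY set from S198 to S202 differed from each of the 2 AA sets at no more than 194 genes. A YY set from S225 to S231 differed from the AA sets at 1744 and 2133 genes. These 2 YY sets differed from each other at 952 genes, and the 2 AA sets at 105. Thus 2 of 4 pairs of an AA and a YY set had fewer called genes than the 2 YY sets. In vitro and in vivo young libraries of 1 pattern differed at 3 genes. Donor and age of the oocyte or of the somatic cells cannot be told apart, because AA, AY and YY share no pattern, and age stays open as untested. Numbering series cannot be told apart from them either, since the groups held separate ranges (YY S198 to S231, AY S234 to S244, AA S268 to S279).

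Granulosa transcripts in AA and AY could come from granulosa RNA carried with the oocyte. Depth is argued against, since mean total counts of AA and AY exceeded those of YY by at most 0.25 SD. The summed markers without Inha and Inhba were higher in AA and AY than in YY (permutation p = 0.00016 and exact permutation p = 0.000485, adjusted p = 8e-04 and 0.00121 over 5 comparisons). Across the 12 AA libraries Inha followed that sum with rho = 0.59 (permutation p = 0.0459, adjusted p = 0.0765 over 5 groups) and r = 0.63 (permutation p = 0.0269, adjusted p = 0.0868), which was 0.41 without the 2 libraries farthest from the median. In AY rho was 0.89 (exact permutation p = 0.0333, adjusted p = 0.0765) and r 0.86 (exact permutation p = 0.0347, adjusted p = 0.0868), which was 0.49 without the 2 libraries farthest from the median. In YY rho was 0.72 (permutation p = 0.0156, adjusted p = 0.0765) and r 0.37 (permutation p = 0.235, adjusted p = 0.294), which was 0.32 without 2 libraries. In vitro young gave rho = 0.33 and r = 0.13 (exact permutation p = 0.428 and 0.772), and in vivo young rho = -0.11 and r = 0.89 (exact permutation p = 0.806 and 0.117), an r that was -0.57 without 2 libraries. The relation did not pass adjustment in any group, so carried RNA and expression by the oocyte cannot be told apart, and age stays an untested explanation.

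Each comparison was set against other splits of its libraries, 100 in each case with the real one included and only the groups compared in the fit. As many genes were called by 1 split, the real one, for AA against YY (2091, highest other 831), AY against AA (876, highest other 65) and YY against in vitro young (190, highest other 98), and by 2 splits for AY against YY (79, highest other 376) and in vitro against in vivo young (20, highest other 29). By these shares chance is excluded only if single libraries can be exchanged, which the pattern sets leave open. For AY against YY and in vitro against in vivo young another split called more genes than the real one. The split of AY and YY that called several times the real count points to a structure of the samples. It set 4 of the 6 YY libraries S225 to S231 with 1 of the 5 libraries S198 to S202, but divided 4 pattern sets, and 2 other splits that parted the YY series in these numbers called 3 genes and 1 gene. Which structure it follows is therefore open. The 2 series of YY libraries differed at 999 genes.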
